A study of Homo sapiens with 8 samples.

How the data were processed

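MicroRNAs (miRNAs) were measured on 8 single-colour Agilent miRNA arrays of 1 slide. The arrays carried RNA from the human pigmented melanoma cell line MNT-1 and from melanosomes isolated from these cells. Melanosomes are the organelles in which melanin is made and stored. Per the labels, pre-mature and mature melanosomes came from a sucrose density gradient, and part of the intact organelles was incubated with RNase at 37 °C, for 10 min, ahead of RNA extraction. The groups were cells (2 arrays), untreated pre-mature melanosomes (1 array), untreated mature melanosomes (1 array), RNase treated pre-mature melanosomes (2 arrays) and RNase treated mature melanosomes (2 arrays). Groups and replicate numbers were taken from the labels. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical. The untreated groups have 1 array each and no spread of their own.

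Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 10.7.3.1, and the processed spot signal is a linear intensity after background correction that can fall below 0. No normalization between arrays had been applied to it by the authors. The files also hold median spot and local background intensities, a summed intensity per miRNA and detection flags. The deposited value table of the series holds linear intensities that the authors had normalized by a method not given in the sources used here. Its columns had medians between 92.7 and 98.1, and it was used only as an alternative. Each array had 62344 spots, of which 60180 belonged to 4774 probes for 2006 miRNAs. No spot was saturated. miRNA names are those of the array files, without the species prefix.

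Spots marked as outliers by Feature Extraction (2.68% to 4.32% of an array's spots) were left out and the remaining spots of a probe were averaged. A probe was taken as well above background where at least a share of 0.5 of its spots carried that mark. Because a share of probes under 0.5 was detected, each array was divided by the 75th percentile of the probes well above background on all 8 arrays. Only 15 probes met that condition, because the untreated mature array had 80 probes well above background. A common floor of 30.3 was then set and log2 taken. The probe with the highest mean stood for its miRNA. miRNAs were tested where at least 1 probe was well above background on every array of at least 1 compared group. A miRNA not well above background on any array of a group has only a bound there. It is given as "at least N-fold", from the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest detected signal and the miRNA's own signal, both on the normalized log2 scale. Such a bound is for the main scaling, and a small one need not hold under another. Among miRNAs with several bright probes, probes pointed in opposite directions for 2 of 391 called miRNAs in the comparison of RNase treated melanosomes with cells.

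Comparisons were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Mature and pre-mature RNase treated melanosomes were compared in a fit of their 4 arrays, and all other comparisons in a fit of all 8 arrays and 5 groups. The smallest two-sided p that an exact permutation of 2 arrays against 2 can give is 0.333, so no single miRNA could pass such a test, and 4 against 2 can give 0.133. Lists of miRNAs fixed before the data were examined were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists with at least 3 tested members, and again with the correlation estimated from the arrays. The lists were pigment cell and melanoma miRNAs, the miR-506 to miR-514 cluster, the let-7 family, the miR-17/92 cluster and paralogs, broadly expressed miRNAs, GC-rich high-number miRNAs, miRNAs matching fragments of other non-coding RNAs, blood and serum miRNAs, the miR-320 family, miRNAs of other tissues, the chromosome 19 cluster and the 14q32 cluster.

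The miRNAs named were fixed by a rule. It takes 9 preset miRNAs, the 10 largest rises and the 10 largest falls past the threshold (or the 10 smallest p where fewer passed), and members of the lists past the threshold, up to 4 a list by size of change, or the 2 brightest members where none passed. Of the members allowed, at most 2 are named per list, and for the comparison of treated with untreated melanosomes only of a list that passed its test. Names of genes that hold a miRNA come from an NCBI gene table of another assembly than the hg19 design of the array, and no coordinates are given. Of 88 miRNAs that the rule gave, 74 had a single gene of that symbol in the table.

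The fits were tested on simulated data with the arrays' own spread. In each of 20 simulations 120 miRNAs were changed at once, and noise was drawn for each miRNA on its own. On the arrays, the estimated correlation within a list reached 0.975 between the stages, so the shares called below need not hold for the arrays themselves. In the comparison of mature with pre-mature RNase treated melanosomes (481 miRNAs), 39.9% of 2-fold, 78.4% of 4-fold and 93.0% of 8-fold changes were called, and 0.956% of unchanged miRNAs. In the comparison of RNase treated melanosomes with cells (528 miRNAs), 67.1% of 2-fold and 93.5% of 4-fold changes were called.

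Alternatives fixed before the data were examined were other scalings (75th percentile over all probes, quantile normalization, no scaling, median of 3 spike-in probes), normexp background correction with an offset of 50, the summed intensity per miRNA, the authors' value table, no filter or a strict filter, a floor 4 times lower or 2 times higher, the mean of a miRNA's probes, eBayes with a trend, the replicate number as a block, other sets of arrays in the fit, and each replicate left out. The normexp correction used the median spot intensity, since the files hold no mean intensity. Alternatives of 3 kinds were chosen after seeing the data, because of the high background of the untreated mature array. These are scaling over the 245 probes well above background on the other 7 arrays, scaling over the 853 probes well above background on the 4 RNase treated arrays, and treated against untreated melanosomes at the pre-mature stage only. Lists were also tested without scaling and with spike-in scaling. The files hold no miRNA sequences, so base composition was not examined.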

Results

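The array data describe which miRNAs were found in MNT-1 cells and in melanosomes of an early (pre-mature) and a late (mature) stage, with and without RNase treatment of the intact organelles. Per the series description, the treatment was meant to take away RNA that adhered to the outside of the melanosome membrane. Of 2006 miRNAs, 215 were well above background on both arrays of cells, 264 in untreated pre-mature melanosomes, 439 on both arrays of RNase treated pre-mature melanosomes and 477 on both arrays of RNase treated mature melanosomes. The untreated mature array gave 50. Its negative-control spots had a median intensity of 3935, against 61 to 67 on the other 7 arrays, and its values are given with that limit. All RNase treated arrays lay in one row of the slide and all other arrays in the other row, so row and treatment cannot be told apart.

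The make-up of the signal differed between cells and melanosomes. In cells, miRNAs matching fragments of other non-coding RNAs took 75.6% ± 5.59 (SD, n = 2) of the summed miRNA signal, led by miR-4454. Their share was 24.4% in untreated pre-mature melanosomes, 4.22% ± 0.990 (SD, n = 2) in RNase treated pre-mature and 4.14% ± 1.17 (SD, n = 2) in RNase treated mature melanosomes. GC-rich high-number miRNAs, a group of late-numbered miRNAs often bright on arrays of vesicle or serum RNA, took 2.02% ± 0.199 (SD, n = 2) in cells, 12.7% in untreated pre-mature melanosomes, and 29.4% ± 1.49 and 27.6% ± 1.46 (SD, n = 2 each) in RNase treated pre-mature and mature melanosomes. Pigment cell and melanoma miRNAs took 3.95% ± 1.23 (SD, n = 2) in cells and 0.901% in untreated pre-mature melanosomes. They took 0.140% ± 0.00867 and 0.196% ± 0.0487 (SD, n = 2 each) in the RNase treated pre-mature and mature groups. Each of these shares on the 4 RNase treated arrays lay outside the range of the 2 arrays of cells. A share does not depend on scaling between arrays, and a fall in a share does not by itself show a fall in amount.

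**Figure D1:**
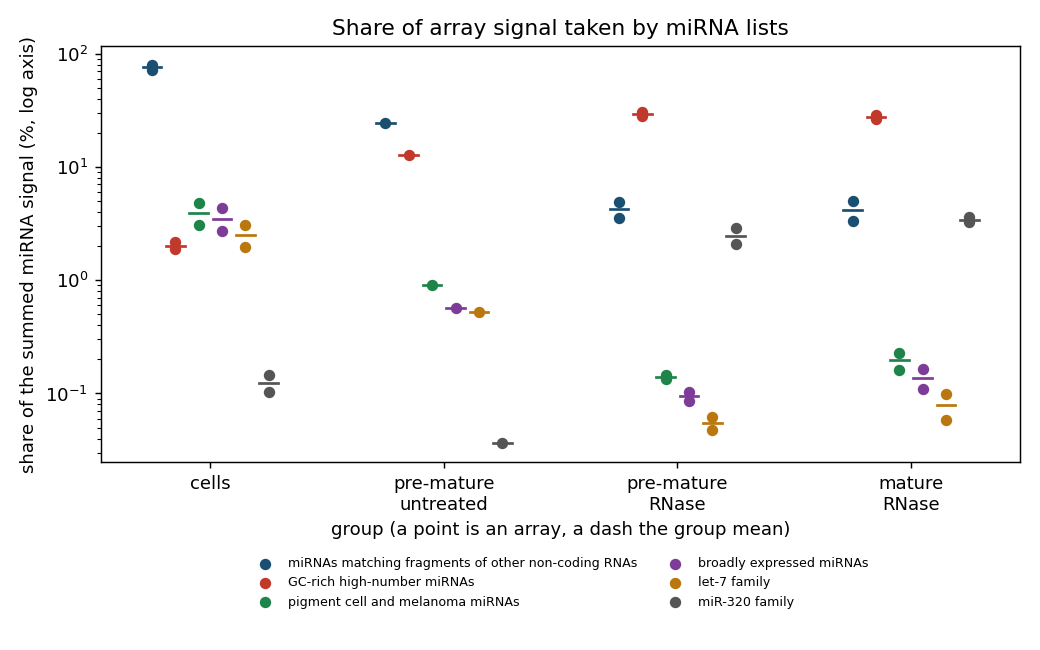
Share of the summed miRNA signal (percent, log axis) taken by 6 miRNA lists on each array (points) and the group mean (dashes), without the untreated mature array. Arrays of the GC-rich list lie at 1.88% to 2.16% in cells and 26.6% to 30.4% after RNase treatment, and those of the pigment cell list at 3.08% to 4.82% and 0.134% to 0.230%.

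The first comparison asked which miRNAs differed between RNase treated mature and pre-mature melanosomes, the pair the series was set up for. No miRNA passed the threshold in this unpaired fit. With the replicate number as a block many did, as given below, but the labels do not say that equal numbers are paired. Of 481 miRNAs tested with limma, 0 had an adjusted p under 0.05, while 117 had an unadjusted p under 0.05, and the median difference over all tested miRNAs was 0.44 (log2, mature minus pre-mature). miR-211-5p, a melanocyte-lineage miRNA whose gene lies within TRPM1, had a scaled log2 signal of 11.54 ± 0.20 (SD, n = 2) in mature and 10.68 ± 0.19 (SD, n = 2) in pre-mature melanosomes, a difference of 0.86 (SE 0.22, adjusted p = 0.162). Differences were 0.81 for miR-21-5p, 0.82 for let-7a-5p, 1.13 for let-7b-5p, 0.39 for miR-1246 and 0.45 for miR-4516. miR-204-5p was well above background on 1 of the 2 mature and on no pre-mature array, and miR-125b-5p and miR-222-3p on none of the 4. The smallest p-values belonged to miR-516b-5p, miR-4728-5p, miR-765, miR-302c-5p, miR-4716-3p, miR-22-3p, miR-6129, miR-1233-1-5p, miR-4721 and miR-4428, whose differences ranged from 0.93 for miR-1233-1-5p to 1.74 for miR-302c-5p, each with an adjusted p of 0.162. miR-516b-5p stood at the floor on both pre-mature arrays, so its difference and its place depend on the floor.

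As groups, 3 lists of abundant miRNAs lay above the other miRNAs in mature melanosomes. The let-7 family (8 tested, median difference 0.81, camera adjusted p = 0.0182), the miR-17/92 cluster and paralogs, a proliferation-linked cluster (10 tested, median 0.87, adjusted p = 0.00468), and broadly expressed miRNAs (18 tested, median 0.84, adjusted p = 0.000128) were 0.36, 0.43 and 0.40 above the median of all tested miRNAs. With an estimated correlation the adjusted p was 0.807 for each of the 3. Adjusted over the list alone, 7, 8 and 16 of their members passed, and 0 over all tested miRNAs. Members of a list moved together (estimated correlation 0.970, 0.975 and 0.867), so these counts are not separate observations. Examples are let-7f-5p at 0.72, miR-19b-3p at 0.92, miR-25-3p at 0.99, miR-29a-3p at 0.87 and miR-16-5p at 0.85. GC-rich miRNAs stood at the median of all miRNAs (31 tested, median 0.45, adjusted p = 0.868), with miR-4281 at 0.17 and miR-1225-5p at 0.18, and 0 passed over the list alone. Unscaled, miR-4281 averaged 290793 in mature against 298043 in pre-mature melanosomes, and miR-1225-5p 215364 against 219138, the other direction.

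The remaining lists did not pass. Pigment cell and melanoma miRNAs had a median of 0.81 over 8 tested members (adjusted p = 0.0922, 5 passing over the list alone). The miR-506 to miR-514 cluster, an X-linked cluster known from melanoma, had 0.27 over 4 (adjusted p = 0.868), with miR-514b-5p at 0.29 and miR-513a-5p at 1.03. The miR-320 family had 0.85 over 5 (adjusted p = 0.229), with miR-320c at 0.85 and miR-320a at 0.75. miRNAs matching fragments of other non-coding RNAs had 0.36 over 8 (adjusted p = 0.229), with miR-4454 at 0.40 and miR-1973 at -0.28. The chromosome 19 cluster had 0.71 over 6 (adjusted p = 0.868), with miR-516a-5p at 0.55 and miR-526b-5p at 1.02. The 14q32 cluster had 0.88 over 4 (adjusted p = 0.238), with miR-134 at 0.97 and miR-494 at 0.80. Blood and serum miRNAs had 0.22 over 3 (adjusted p = 0.888), with miR-423-5p at 0.86 and miR-486-5p at 0.22. Of the miRNAs of other tissues too few were tested, and miR-133a and miR-133b stood at 0.02 and 0.10.

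The calls of these 3 lists changed with the scaling and with an array left out. With the 75th percentile over all probes the let-7 family did not pass (adjusted p = 0.0678) and GC-rich miRNAs passed as lower (median -0.22, adjusted p = 0.0176). The 3 calls were absent with quantile normalization and with scaling over probes of the RNase treated arrays, where the median of all miRNAs was 0 and broadly expressed miRNAs stood at 0.13 and 0.07, and absent without replicate 2 of RNase treated pre-mature melanosomes, where the list of miRNAs matching other RNAs passed, below the other miRNAs (adjusted p = 0.0204). With the former 2 scalings the miR-320 family passed instead (medians 0.21 and 0.22, adjusted p = 0.041 and 0.0074), and with scaling over 7 arrays no list passed. Without replicate 1 of RNase treated mature melanosomes the 3 lists passed as higher, although their medians, 0.59 to 0.67, lay below the median of all miRNAs, 0.68. No count changed with scaling for single miRNAs, since 0 passed under each.

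**Figure D2:**
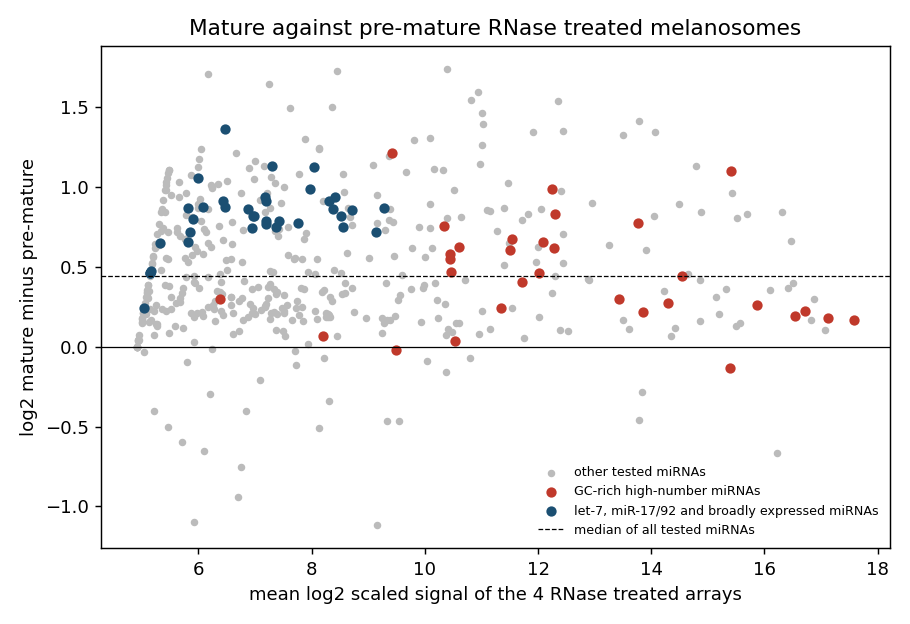
Log2 difference between mature and pre-mature RNase treated melanosomes (vertical axis) against mean log2 scaled signal of the 4 arrays (horizontal axis), one point per tested miRNA. The 36 miRNAs of 3 lists abundant in cells range from 0.24 to 1.36, with list medians of 0.81 to 0.87 against the dashed median of all tested miRNAs at 0.44, and GC-rich miRNAs spread around that median under the scaling shown.

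RNase treated melanosomes were next compared with whole cells. The cells were not RNase treated and lay in the other row of the slide. In this contrast alone, organelle, treatment and row cannot be told apart. The 1 untreated pre-mature array lay in the row of cells. Mean scaled log2 signal of the let-7 list was 10.4 and 10.1 on cells and 7.40 on that array. On RNase treated pre-mature arrays it was 6.74 and 6.76. In the same order, broadly expressed miRNAs had 8.76 and 8.48, 6.06, and 5.94 and 6.01. Low signal of these lists was thus also seen without RNase, on 1 array. The GC-rich list had 8.07 and 8.21, 9.79, and 11.89 and 12.22. miRNAs abundant in cells were far lower in RNase treated melanosomes and GC-rich high-number miRNAs far higher. All 9 measured let-7 members fell (median -3.26, camera adjusted p = 5.25e-07), all 12 tested members of the miR-17/92 cluster and paralogs fell (median -3.14, adjusted p = 1.16e-08), and all 23 tested broadly expressed miRNAs fell (median -3.01, adjusted p = 2.9e-15). Of pigment cell and melanoma miRNAs 13 of 15 fell and none rose (median -2.50, adjusted p = 3.13e-08). Of GC-rich high-number miRNAs 30 of 31 rose and 1 fell (median 3.91, adjusted p = 7.1e-05). With an estimated correlation the adjusted p was 0.355 for the 4 lists that fell and 0.445 for the GC-rich list. The GC-rich list also did not pass with quantile normalization (adjusted p = 0.315) or scaling over 7 arrays (adjusted p = 0.0914). Members of the lists included miR-30b-5p (-3.34) and miR-148a-3p (-3.28) of the pigment cell list, miR-24-3p (-3.32) of the broadly expressed list, and miR-1207-5p (8.49) and miR-1225-5p (8.35) of the GC-rich list.

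Among single miRNAs, miR-211-5p changed by -2.76 (log2, SE 0.18, adjusted p = 0.000133) against a scaled signal of 13.87 ± 0.24 (SD, n = 2) in cells. miR-21-5p changed by -2.57, let-7a-5p by -3.40 and let-7b-5p by -3.09. miR-204-5p, which lies within TRPM3, changed by -2.31, on the floor in melanosomes, and was well above background on 1 of 4 melanosome arrays. miR-125b-5p was at least 3.69-fold lower. miR-222-3p was not well above background in either. miR-4516 rose by 3.55 (SE 0.09), but stood at -0.86 with quantile normalization, -0.10 with scaling over 7 arrays and -0.020 in the authors' values. miR-1246 stood at 0.72 (SE 0.37, adjusted p = 0.134) and was below 0 under 6 other settings, from -0.16 with the 75th percentile over all probes to -2.93 with scaling over 7 arrays. The 10 largest falls were miR-3651, at least 20.7-fold lower, and miR-5100 (-4.08), miR-1260a (-4.03), miR-1260b (-3.91), miR-93-5p (-3.81), let-7d-5p (-3.52), miR-30c-5p (-3.50), miR-17-5p (-3.48), let-7g-5p (-3.46) and let-7f-5p (-3.46). The 10 largest rises included miR-6510-5p, at least 929-fold higher, miR-652-5p, at least 499-fold, miR-4669, at least 449-fold, miR-1185-1-3p, at least 301-fold, miR-4534, at least 298-fold, and miR-198, at least 268-fold higher, which were not well above background in cells. miR-4270 (9.90) and miR-5787 (9.43) were well above background on both arrays of cells, and miR-4499 (9.81) and miR-134 (9.54) on 1 of them. Under scaling over 7 arrays, the changes of these 10 were also positive. On the untreated pre-mature array these 10 stood at 4.92 (miR-198) to 9.20 (miR-5787) in scaled log2 signal. On the RNase treated arrays of that stage they averaged 13.39 (miR-1185-1-3p) to 17.02 (miR-4270).

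Other lists behaved as follows. miRNAs matching fragments of other non-coding RNAs fell as a list (5 lower, 1 higher, median -1.79, adjusted p = 0.022), with miR-1973 changing by 6.01 and miR-5100 by -4.08. Its adjusted p was 0.355 with an estimated correlation, 0.0908 without replicate 2 of cells 0.0522 without replicate 1 of RNase treated mature melanosomes, 0.149 with normexp correction and 0.115 with scaling over 7 arrays, and its median was 0.23 with spike-in scaling. The miR-320 family did not pass (3 higher, 1 lower, adjusted p = 0.903), with miR-320c changing by 8.49 and miR-320a by 2.98, the latter at -0.67 with scaling over 7 arrays and -0.089 over the RNase treated arrays. The miR-506 to miR-514 cluster (1 higher, 1 lower of 4, adjusted p = 0.398) held miR-514b-5p, at least 20.9-fold higher, and miR-513b, which changed by -0.996 but by 0.19 without scaling and 0.40 with spike-in scaling. The chromosome 19 cluster (4 higher of 6, adjusted p = 0.398) held miR-516a-5p and miR-526b-5p, at least 3.98-fold and 2.86-fold higher. In the 14q32 cluster all 4 tested members rose (adjusted p = 0.398), with miR-665 at least 1.06-fold higher, though it was at -0.24 with normexp correction. Blood and serum miRNAs (1 lower of 3, adjusted p = 0.441) held miR-423-5p at -1.03, which was 0.43 without scaling and 0.99 with spike-in scaling. miRNAs of other tissues (2 higher, 2 lower of 4, adjusted p = 0.393) held muscle miR-133a and miR-133b, at least 4.28-fold and 3.17-fold higher. These bounds, and those of the chromosome 19 cluster, are for the main scaling and need not hold with scaling over 7 arrays. Adjusted over the list alone the numbers past the threshold were 13 for the pigment cell, 9 for the let-7, 12 for the miR-17/92, 23 for the broadly expressed and 31 for the GC-rich list, and 6, 4, 2, 4, 4, 1 and 4 for the lists in the order just given.

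Of 528 miRNAs tested, 433 passed, 314 higher and 119 lower in RNase treated melanosomes than in cells, around a median shift of 1.37. That shift was 0.75 with the 75th percentile over all probes, 1.95 without scaling, 2.16 with spike-in scaling and 0 with quantile normalization and the scalings over 7 or over 4 arrays. The split became 195 higher and 169 lower with quantile normalization, 370 and 64 with spike-in scaling, 115 and 188 with scaling over 7 arrays, and 150 and 176 over the RNase treated arrays. With normexp correction it was 202 and 193, around a median of -0.039. The medians of the let-7 family lay between -6.52 and -1.38 and those of the pigment cell list between -3.33 and -0.74 over these scalings, and those of the GC-rich list between 0.26 and 5.93. At the pre-mature stage 408 of 496 passed (284 higher, 124 lower). The split there was 186 and 162 with quantile normalization, 339 and 85 without scaling, 336 and 73 with spike-in scaling, 104 and 184 over 7 arrays, 148 and 167 over the RNase treated arrays, and 176 and 174 with normexp correction. At the mature stage 443 of 524 passed (331 higher, 112 lower), with 184 and 168, 384 and 32, 111 and 182, and 145 and 170 under quantile, spike-in, 7-array and RNase-array scaling, and 215 and 152 with normexp correction. With the strict filter the 3 counts were 141, 143 and 151.

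**Figure D3:**
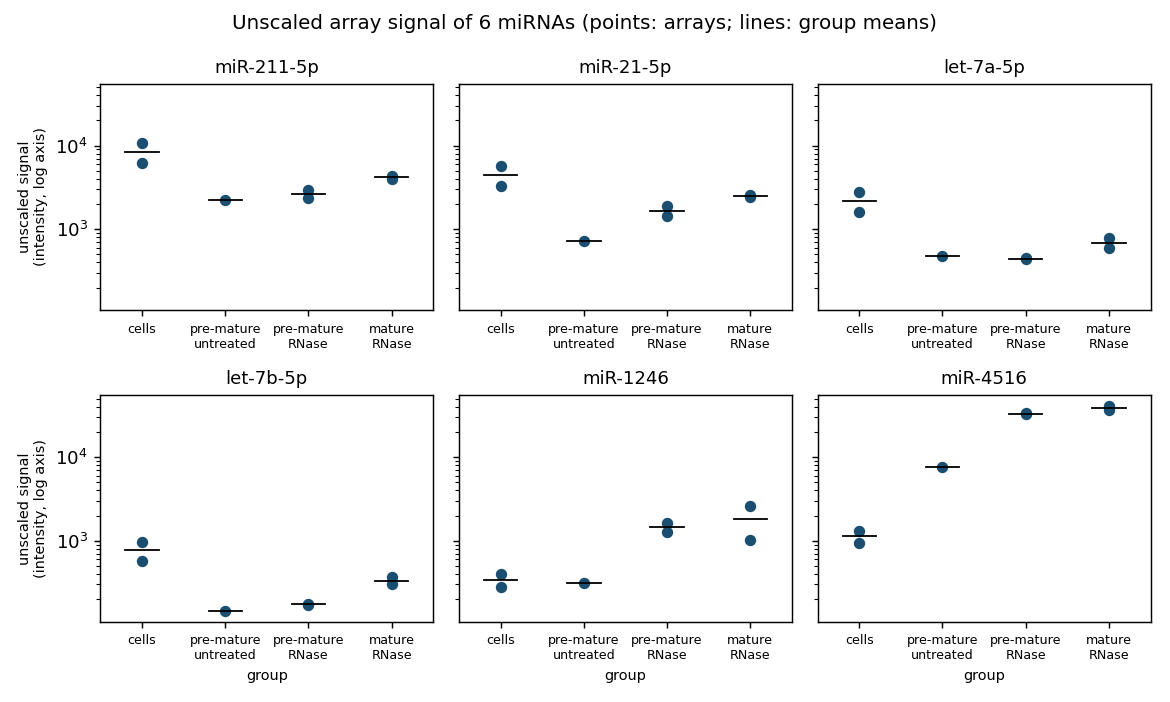
Unscaled intensity (log axis) of 6 miRNAs fixed before the data were examined on each array (points) with group means (lines), without the untreated mature array. Unscaled miR-211-5p averaged 8460 in cells, 2663 in RNase treated pre-mature and 4182 in RNase treated mature melanosomes, and miR-4516 averaged 1129, 33157 and 39307. On the untreated pre-mature array miR-211-5p was at 2214 and miR-4516 at 7687.

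RNase treated and untreated melanosomes were compared to see what the treatment changed. Each stage had 1 untreated array, so the p-values take the untreated spread from the replicated groups and assume that the untreated arrays vary like those. Where a miRNA stood at the floor on all replicated arrays, as miR-885-5p did, that spread was 0. Over both stages 420 of 532 miRNAs passed, 243 higher and 177 lower after treatment, with a median shift of 0.42. The split was 268 and 89 with the 75th percentile over all probes, 283 and 116 without scaling, 287 and 100 with spike-in scaling, 96 and 342 over 7 arrays, and 137 and 266 over the RNase treated arrays. It was 126 and 341 with normexp correction, 380 and 104 with summed intensity, and 303 and 131 in the authors' values. On the untreated mature array 0 miRNAs of the GC-rich list, the let-7 family, the miR-17/92 list, the broadly expressed list and the miR-320 family were well above background. Their values there are the floor or background signal, so sizes of change and calls over both stages are not exact. GC-rich high-number miRNAs passed as higher (27 higher, 3 lower of 31, median 4.29, camera adjusted p = 7.35e-05, and 0.855 with an estimated correlation), and this median was 1.91 at the pre-mature stage alone. With quantile normalization the list's adjusted p was 0.113, and at the pre-mature stage alone it was 0.113 as well. The 10 largest rises were those of miR-320c, miR-4270, miR-6510-5p, miR-5787, miR-642a-3p, miR-1202, miR-6165, miR-652-5p, miR-4499 and miR-4534. Each was at the floor on the untreated mature array, so their sizes and order over both stages are not given. At the pre-mature stage alone miR-642a-3p changed by 7.12 and miR-4499 by 7.24. The 10 largest falls (miR-197-3p, miR-574-3p, miR-4254, miR-3591-3p, miR-885-5p, miR-4649-3p, miR-328, miR-3617-3p, miR-204-5p and let-7d-3p) carried the high-background untreated mature array, on which 7 of them were well above background, and each but miR-4649-3p stood at the floor after treatment, so their sizes are not given. miR-211-5p, well above background on both untreated arrays, changed by -1.51, but by 1.34 with the 75th percentile over all probes. let-7b-5p, miR-4516, miR-1246, miR-21-5p and let-7a-5p were not well above background on the untreated mature array. At the pre-mature stage alone miR-1246 stood at 1.40 (adjusted p = 0.0911), let-7b-5p at -0.52, miR-21-5p at 0.38 and let-7a-5p at -0.92, none past the threshold. Of these, each but let-7a-5p had the other sign there under at least 1 setting. miR-125b-5p and miR-222-3p were not well above background in any melanosome array. No other list passed. The medians were -0.96 for the let-7 family (4 lower of 8), -0.91 for the miR-17/92 list (3 higher, 6 lower of 10), -0.11 for broadly expressed miRNAs (5 higher, 8 lower of 18) and 0.11 for pigment cell miRNAs (3 higher, 4 lower of 9). They were 4.16 for the miR-320 family (5 higher of 5), -1.49 for the miR-506 to miR-514 cluster (1 higher, 3 lower of 4), -0.72 for miRNAs matching other RNAs (2 higher, 4 lower of 8), -1.43 for blood and serum miRNAs (1 higher, 2 lower of 3), -0.39 for the chromosome 19 cluster (2 higher, 1 lower of 6) and 0.85 for the 14q32 cluster (3 higher, 1 lower of 4).

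Without the untreated mature array, a choice made after its background was seen, the comparison holds 2 treated arrays and 1 untreated array of the pre-mature stage. The untreated array has no replicate, so the p-values take its spread from the replicated groups in the fit and assume that it varies like them. Of 471 miRNAs 304 passed (238 higher, 66 lower, median shift 1.18). The miR-320 family rose in all 5 members (median 3.58, adjusted p = 0.106 as a list), with miR-320c at 10.40 (SE 0.45) and miR-320a at 4.19 (SE 0.41), and its median stayed above 0 under each scaling, at 0.11 to 4.16. Of the miR-506 to miR-514 cluster 3 of 4 tested members fell and 1 rose (median -2.84, adjusted p = 0.0116, and 0.629 with an estimated correlation). miR-513b was at least 14.2-fold lower after treatment and miR-514b-5p at least 30.7-fold higher. The medians of the let-7 family (-0.80, 3 lower of 8, adjusted p = 0.00239) and of broadly expressed miRNAs (-0.39, 2 higher and 3 lower of 17, adjusted p = 0.0115) lay below that of all miRNAs, with an adjusted p of 0.763 with an estimated correlation for both, and unscaled they were -0.05 and 0.41. In the let-7 family let-7d-5p changed by -0.96 and let-7f-5p by -0.89. Of GC-rich miRNAs 22 rose and 4 fell (median 1.91, adjusted p = 0.113), with miR-1202 at 7.05 and miR-1275 at 6.64, but the list's median was -1.57, -1.06 and -0.76 with the 7-array, quantile and RNase-array scalings.

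Further large rises were miR-4270 (9.22), miR-6510-5p (8.86), miR-652-5p (8.25), miR-6165 (8.08), miR-5787 (7.55) and miR-4442 (7.45). miR-198, miR-4534 and miR-1185-2-3p, not well above background untreated, were at least 352-fold, 346-fold and 209-fold higher. The largest falls were miR-4428 (-4.83), miR-6132 (-3.84), miR-513b, miR-4299 (-3.69), miR-513a-5p (-3.65), miR-1233-1-5p (-3.49), miR-4465 (-3.44), miR-197-3p, at least 9.08-fold lower, miR-4728-5p (-2.91) and miR-378a-3p, at least 6.32-fold lower. miR-6132 stood at the floor on both treated arrays, so its value and place are set by the floor. miR-4516 rose by 1.31 (SE 0.09), a value that turned negative under 4 other settings, and miR-211-5p stood at -0.54 (SE 0.24, adjusted p = 0.126). Unscaled, miR-211-5p went the other way, at 2214 on the untreated array and 2663 on average after treatment. miR-494 changed by -1.63 and miR-134 by 5.77, both of the 14q32 cluster. miR-30d-5p was at least 4.21-fold higher and miR-221-3p changed by -0.63. Under at least 1 other setting the signs of miR-30d-5p, miR-221-3p, miR-29b-3p, miR-30e-5p, miR-423-5p, miR-1973 and miR-516a-5p were the other way. miR-29b-3p rose by 2.05, miR-30e-5p at least 1.86-fold and miR-423-5p at least 1.52-fold, miR-1973 changed by -0.58, and muscle miR-133a and miR-133b were at least 6.90-fold and 4.97-fold higher. Of the chromosome 19 cluster miR-1323 was at least 3.82-fold higher and miR-516a-5p changed by 1.87. Under the main scaling the untreated array was divided by 0.929 and the treated arrays by 1.61 and 1.63. With scaling over 7 arrays these factors were 0.263, 4.40 and 5.85, so bounds of this size need not hold there. The split of higher and lower calls was 192 and 126 with the 75th percentile over all probes, 145 and 176 with quantile normalization, 277 and 34 without scaling, 272 and 34 with spike-in scaling, 77 and 214 over 7 arrays, and 112 and 179 over the RNase treated arrays. It was 264 and 126 with summed intensity and 224 and 180 in the authors' values. The lists of pigment cell miRNAs (median -0.27, 1 higher, 1 lower of 7, adjusted p = 0.106), the miR-17/92 list (-0.18, 0 called of 10, adjusted p = 0.0565), miRNAs matching other RNAs (0.17, 1 lower of 8, adjusted p = 0.251), blood and serum miRNAs (0.82, 1 higher of 3, adjusted p = 0.854), the chromosome 19 cluster (1.43, 2 higher of 6, adjusted p = 0.825) and the 14q32 cluster (0.43, 1 higher, 1 lower of 4, adjusted p = 0.704) did not pass. A single untreated array stands behind each of these differences.

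Whether the effect of treatment differed between the stages was tested as an interaction. It passed for 344 of 532 miRNAs (152 higher, 192 lower), but 1 untreated array per stage enters it and the mature one had the high background. The split depended on the processing. It was 221 higher and 29 lower with the 75th percentile over all probes, 215 and 79 with quantile normalization, 111 and 180 without scaling, 116 and 174 with spike-in scaling, 185 and 202 over 7 arrays, and 202 and 164 over the RNase treated arrays. It was 3 higher and 449 lower with normexp correction, 261 and 68 with summed intensity, and 325 and 97 in the authors' values. With the strict filter 11 miRNAs were tested and 4 passed.

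Detected miRNAs overlapped between the stages. Of the 439 miRNAs well above background on both RNase treated pre-mature arrays, 435 were so on both mature arrays. 11 miRNAs were found on both mature arrays and on neither pre-mature array, and 2 the other way round, miR-3935 and miR-4269, named here after their values were seen. On the scaled values both of the latter stood at the floor on the 4 arrays, with a difference of 0 between the stages, and the 11 differed by 0 to 0.56. Of the 435 shared miRNAs, 266 were not well above background on any array of cells, while 34 miRNAs of cells were found on none of the 4 RNase treated arrays. Of the 435, 177 were found on no array of cells or of untreated melanosomes, so only on the RNase treated arrays of the one row.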

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

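The test of the background below was chosen after the result was seen.

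The interaction of stage and RNase treatment, a test of whether the treatment's effect differed between mature and pre-mature melanosomes, passed for 344 of 532 miRNAs, 152 higher and 192 lower. It stood out because 2 stages differed under the same contrast. It rests on 1 untreated array per stage. The split went from 221 higher and 29 lower with the 75th percentile over all probes to 3 higher and 449 lower with normexp correction, so its direction depends on the processing.

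The untreated mature array had a negative-control median 58.7 times the highest of the other 7 arrays (3935 against 67), so a raised background over the whole array is a candidate explanation for much of this difference. With the strict filter, which asks for signal in every compared group, 11 miRNAs were tested and 4 passed. What raised the background is not in the files. A difference in biology between the stages stays open and was not tested apart from this array.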

How the results depend on the processing

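The scalings over 7 arrays and over the RNase treated arrays, the comparison at the pre-mature stage, and the list tests without scaling and with spike-in scaling were chosen after seeing the data. Where no cause is given below, the cause was not tested.

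For mature against pre-mature RNase treated melanosomes 0 miRNAs passed under each alternative except the replicate number as a block, where 211 passed. Of the 211, 203 were higher and 8 lower in mature melanosomes. The labels do not say that replicates of equal number are paired. Across 481 miRNAs, which are not independent, the deviations of equal numbers correlated at 0.804 between the RNase treated groups, and at 0.225 and 0.289 between cells and the pre-mature and mature groups. In the same order they were 0.727, 0.0123 and 0.106 with quantile normalization, and 0.762, 0.194 and 0.295 with scaling over the RNase treated arrays. The number of lists that passed went from 3 to 0 with an estimated correlation or scaling over 7 arrays. It was 1 with quantile normalization and 1 over the RNase treated arrays, in both the miR-320 family and none of the 3. It was 1 with the block, where none of the 3 passed and miRNAs matching other RNAs were lower (adjusted p = 0.0274), and 1 to 3 with a replicate left out.

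With the strict filter, which tests fewer miRNAs, 141 passed for RNase treated melanosomes against cells, 143 at the pre-mature and 151 at the mature stage, and scaling over 7 arrays gave 293 at the mature stage. The 6 lists became 0 with an estimated correlation. For treated against untreated melanosomes 1184 passed without a filter and 9 with the strict filter, and for the interaction 1106 and 4. At the pre-mature stage the counts were 140 and 155. The number of lists went from 1 to 0 with an estimated correlation, 0 with quantile normalization and 3 at the pre-mature stage, where the 3 were lower and the GC-rich list did not pass. Detected miRNAs of the untreated mature array were 167 by Feature Extraction's own call and 32 where every spot had to be above background. Its high background limits what it can detect.

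Single miRNAs took the other sign as follows, for melanosomes against cells. miR-1246 was -1.98 with quantile normalization, -1.46 with summed intensity, -1.43 in the authors' values, -2.93 over 7 arrays and -2.35 over the RNase treated arrays. miR-4516 was -0.86 with quantile normalization, -0.020 in the authors' values and -0.099 over 7 arrays. miR-513b was 0.19 and 0.40, and miR-423-5p 0.43 and 0.99, without scaling and with spike-in scaling. miR-320a was -0.67 and -0.089 over 7 and over the RNase treated arrays, and miR-665 -0.24 with normexp correction.

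For treated against untreated melanosomes, miR-211-5p was 1.34 and let-7b-5p 0.21 with the 75th percentile over all probes. let-7a-5p was 1.54 and let-7b-5p 1.27 with summed intensity. miR-21-5p was -3.27 and -1.14 over 7 and over the RNase treated arrays. miR-4516 was -0.13 with quantile normalization, -0.15 in the authors' values and -1.90 over 7 arrays.

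At the pre-mature stage, quantile normalization gave -3.07 for miR-21-5p, -1.10 for miR-1246, -2.19 for miR-4516, -0.33 for miR-30e-5p and -0.16 for miR-423-5p. The authors' values gave -1.93, -0.86, -2.02, -0.21 and -0.21 for the same 5. Scaling over 7 arrays gave -3.09, -2.07, -2.16, -0.78 and -0.37 for these, -0.22 for miR-30d-5p, -1.42 for miR-29b-3p and -1.40 for miR-516a-5p. Scaling over the RNase treated arrays gave -2.28 for miR-21-5p, -1.35 for miR-4516, -0.61 for miR-29b-3p, -0.71 for miR-30e-5p, -0.30 for miR-423-5p and -0.79 for miR-516a-5p. The 75th percentile over all probes gave -0.11 for miR-30e-5p. miR-221-3p was 0.17 and 0.21, and miR-1973 0.22 and 0.25, without scaling and with spike-in scaling.

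Among the other values of named miRNAs, 940 kept direction and side of the threshold for melanosomes against cells and 35 lost the call. For melanosomes against cells 3 gained a call, and miR-1246 took the other sign without a call with the 75th percentile over all probes (-0.16). For mature against pre-mature 732 kept both, 62 took the other sign without a call, and 20 gained a call, each with the replicate block. For treated against untreated melanosomes 553 kept both, 13 lost and 11 gained the call and 5 took the other sign without a call. At the pre-mature stage these were 826, 89, 42 and 12.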

Other observations

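The tests of whole-array brightness and of background hybridisation below were chosen after the result was seen. The tests of probe ratios, of signal level and of the spread between arrays were written before it.

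Control probes outside the miRNA comparisons also differed between groups. Probes named hur_1, hur_2, hur_4, hur_6 and mr_1 were 16.3, 44.9, 59.5, 39.7 and 35.6 times as bright in cells as in RNase treated melanosomes. The mean intensity of hur_5 was 328 in cells and at the level of the negative control after RNase treatment, so no ratio is given. The mean intensity of hur_1 was 199328 in cells (n = 2), 93857 in untreated pre-mature melanosomes and 12208 ± 1088 (SD, n = 4) after RNase treatment. The control probes dmr_285, dmr_6 and dmr_31a differed by 1.05, 1.04 and 1.12 times, and dmr_3 by 3.11 times. Other controls went the other way. The bright-corner control had a mean intensity of 84.1 in cells, 66.0 in untreated pre-mature melanosomes and 407 ± 44.8 (SD, n = 4) after RNase treatment, and 1 negative control probe had 7.31, 7.14 and 18.6 ± 6.0 (SD, n = 4). That probe stood at 12.6 and 24.0 on replicates 1 and 2 of the treated pre-mature group, and at 14.4 and 23.6 on those of the mature group. The other negative control probes were 1.02 to 1.48 times as bright in cells as after RNase treatment. The files do not say what the names stand for. The 3 probes taken as spike-ins for scaling came from the dmr controls given above. The factors of that scaling were 1.34 and 1.25 on cells and 0.799 to 0.950 on the RNase treated arrays. They differ by more than dmr_285, dmr_6 and dmr_31a do, so spike-in scaled values may carry the difference of dmr_3.

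GC-rich high-number miRNAs were brighter after RNase treatment, under the main scaling. Brighter labelling or scanning of the whole array would raise lists alike. At the pre-mature stage the unscaled medians of the GC-rich and the broadly expressed list moved apart by 2.30 (log2). The spread of that difference was 0.239 between the treated replicates, and the untreated array has no replicate. Unscaled, the median of all tested miRNAs also rose by 1.84 (log2) at this stage. Whole-array brightness would thus not move the lists apart, but may stand behind part of the GC-rich rise. Background hybridisation raised over the whole array would raise the negative controls, but the ratio of their medians was 1.01 while the GC-rich list rose 6.53-fold. The median does not exclude binding to single probes, since 1 negative control probe and the bright-corner control given above were brighter after treatment. The other negative control probes were not brighter than in cells. Labelled fragments of other RNAs that bind part of the probes would change the ratio between probes of 1 miRNA. Fragments that bind all its probes alike would not, so the ratio cannot show those. From cells to RNase treated melanosomes that ratio moved by a median of 0.0916 in 22 GC-rich miRNAs and 0.0229 in 25 miRNAs of the 3 other lists, a gap of 0.0687 (permutation p = 0.00014). The permutation moved miRNAs between lists as if they were independent, and 2 arrays of cells stand behind every ratio. The gap goes the way that explanation needs, but it is small beside the rise, and a curved response at high signal may give it as well. RNA fragments made by the RNase itself, RNA protected inside melanosomes and the array row were not told apart, since every RNase treated array lay in the same row.

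miRNAs of the let-7, miR-17/92 and broadly expressed lists, abundant in cells, stood higher in mature than in pre-mature RNase treated melanosomes. A difference that depends on signal level was tested with random lists matched on mean signal. The median of the 36 miRNAs, 0.82, was at percentile 100 of these, against 0.54 at the percentile set beforehand as the limit. The 36 are members of the lists that passed in this same fit. They moved together (estimated correlation of 0.867 to 0.975 within a list), which the random lists do not copy. The percentile therefore does not decide whether signal level plays a part. Unless replicates of equal number are paired, which the labels do not say, the spread between arrays of one group can give a shift of this size. Against all tested miRNAs the 36 shifted by 0.380 between the stages, and by up to 0.712 between replicates of one group, 1.87 times as much. Over the 4 pairs of a mature and a pre-mature array the shift ranged from -0.24 to 0.83, both from pairs of unequal replicate number. For replicates 1 it was 0.58 and for replicates 2 it was 0.21. A difference between the stages stays open as a hypothesis.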
